A study of Mus musculus with 12 samples.

How the data were processed

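The series measured miRNAs in total RNA of mouse liver with one-colour (Cy3) Agilent miRNA arrays, 12 arrays for 12 times of collection 4 h apart. Per the labels' protocols, total RNA was extracted with TRIzol, its quality was checked on a Bioanalyzer, and the RNA of the livers of a time was mixed in equal amounts before labelling. The values deposited for each array are spot intensities on a linear scale, subtracted for background and detrended within the array by Agilent Feature Extraction, per the file headers. The headers name version 10.7.3.1 and the submitters' processing notes name version 9.5.3.1, and the values were used as the files hold them. No scaling between arrays had been applied to these intensities, and some lie below 0. The series value table holds the same deposited intensities: each spot differed by 0 from the processed signal of its scanner file, so its scale, centring and direction are known. Its column medians lay between 0.661 and 4.12 intensity units, since most spots carry no signal. No genome build is named in the sources used here, so no coordinates are given, and miRNA names are those of the array design. The series text gives another number of mouse miRNAs than the files, which hold 611 mouse entries and 39 herpesvirus entries on 1857 probes.

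Clock time, cycle and lights were taken from the collection times in the sample titles. Spots that the scanner software marked as outliers (3.82% to 6.94% of an array) and control spots were left out, and the remaining spots of a probe were averaged. No spot was saturated (0 on each array). Each array was scaled to its 75th percentile over the 157 probes detected on all 12 arrays, a probe being detected where more than 50% of its spots were well above background. The scaling factors lay between 0.9097 and 1.156. A floor of 21.9 intensity units, the median over arrays of the lowest scaled signal among detected probes, was then set on every array, and log2 was taken. Each miRNA was represented by its probe with the highest mean over all arrays. Only 2 tested miRNAs had 2 or more probes detected on all arrays, and the median r between their probes over the arrays was 0.618. Entries that the software called detected on at least 6 of the 12 arrays were tested, 139 in all. Among them, 5 (miR-219, miR-301a, miR-340-5p, miR-378* and miR-467f) lay at the floor on all 12 arrays. They were kept in the tests, as the design fixed before the data were examined has it, and carry no information of their own. They do enter the variance that limma shares between entries. Its prior degrees of freedom in the 24-h test were 0.905 with them and 2.18 without, and 0 entries passed either way. They also count among the 139 in every number expected by chance. Values at the floor have no order, and upper limits of a peak-to-trough fold are given only for the 109 entries never at the floor.

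Tests used limma 3.58.1 in R 4.3.3, and files were read with the package data.table, version 1.17.8. Each comparison was a linear model on the log2 values with a moderated variance that depended on intensity, and p-values were adjusted by Benjamini-Hochberg over the 139 entries at a threshold of 0.05. The 24-h rhythm was an F test of a cosine and a sine with a period of 24 h; light against dark was the mean of 6 dark arrays minus that of 6 light arrays; the time of day was an F test over 6 clock times; the cycle was tested with clock time in the model; and the 12-h rhythm was tested beside the 24-h terms. The upper 95% limit of a peak-to-trough fold came from the joint confidence region of both terms. The 24-h test was repeated by permuting the 12 time labels (100000 draws, the smallest possible p being 1e-05). Resemblance of arrays 24 h apart was tested by an exact permutation over all pairings. Each test was run on simulated data, 20 sets per fold size with 20 of 139 entries changed and the spread of the real entries. The simulated values were drawn independently for each entry from a normal distribution, and no floor was set on them. Real entries can vary together and lie at the floor, so the shares recovered and the shares of false calls need not hold for them. The share of false calls was between 3.19% and 8.3%, except 26.5% for the time-of-day test at 1.2-fold, where few calls were made.

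In all, 22 lists of miRNAs were fixed before the data were examined: clock-related, hepatocyte, lipid and glucose metabolism, let-7, miR-30, miR-29, miR-17~92, miR-15/16, miR-23/27/24, miR-200, miR-183, leukocyte, red cell, endothelial, mesenchymal, striated muscle, neuronal, pancreatic, Dlk1-Dio3, Sfmbt2, RNA quality and herpesvirus. Some miRNAs belong to several lists. Lists with at least 2 tested members were tested for a 24-h rhythm of their mean standardised value by permutation of the time labels, and between light and dark by camera with a preset correlation of 0.01, with fry beside it. A list entry matched a name without its species prefix, with either arm where none was given.

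The miRNAs named were chosen by a rule fixed beforehand. For each comparison it took those past the threshold and otherwise the smallest p-values, 10 for the 24-h rhythm and 5 for each of light against dark, time of day and cycle. It added miR-122, let-7a, miR-21, miR-22, miR-378, the tested clock-related miRNAs, and up to 4 members of each list with the smallest 24-h p-values. Others, those of the 12-h test, of other list members and of single arrays among them, were picked after their values were seen.

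The alternatives fixed beforehand were scaling on all probes, quantile normalization, no scaling, normexp background correction (offset 50), a filter to entries detected on all 12 arrays, no filter, the mean of all probes, the total gene signal of the software, a floor of 1/2 of the main one, the value table, the slide as a block, each array left out in turn, each slide alone, the cycle as a block, a linear trend, and a threshold of 0.1. The normexp correction was planned on the mean signal and run on the median signal, the one the files hold. Without a filter limma could not fit its variance trend, since 410 of the mouse miRNAs lay at the floor on all 12 arrays, so that alternative was run on the other 201. Added after seeing the data were the column of the slide as a block, leaving out the ZT22 and ZT50 arrays, leaving out the 5 entries at the floor, normexp with unmoderated variances, and further runs on single slides. The cycle was used as a block only as an alternative, since arrays of one cycle come from different mice. The ZT22 and ZT50 arrays were doubted because they stood apart on principal components 2 and 3 (2.4 and 1.57 for ZT22, -2.01 and 1.62 for ZT50).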

Results

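MicroRNAs (miRNAs), short RNAs that repress messenger RNAs with complementary sites, were measured in mouse liver over 2 days of a light-dark schedule. Adult mice lived in 12 h of light and 12 h of dark with free access to food and water, and zeitgeber time (ZT) counted the hours from a lights-on. Livers were taken every 4 h from ZT18 to ZT62. The RNA of 2 livers was pooled in equal amounts at each time and hybridised to 1 array, so 12 pools stood on 12 arrays. They fell on 6 clock times (2, 6, 10, 14, 18 and 22 h after lights on) with 2 arrays each, 24 h apart, 6 arrays in the light and 6 in the dark. The first array of each clock time is called cycle 1 here and the later one cycle 2. The replicates were pools taken 24 h apart, so the p-values below measure the spread between pools of 2 livers, together with labelling and hybridisation, and not the spread between mice. Only the time-of-day and cycle tests fitted each clock time. In the other tests this spread also holds differences between clock times that the model leaves out.

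The arrays held 611 mouse miRNA entries and 39 herpesvirus entries, the latter serving as a background list. Between 132 and 162 entries were detected on an array, 112 were detected on all 12 arrays and 427 on none. The 139 entries detected on at least 6 arrays were tested, 135 of them mouse miRNAs and 4 herpesvirus entries. Between 16.5% and 19.6% of the spots on an array lay well above background. The profiles of any 2 arrays correlated with r of at least 0.987 and a median of 0.994, taken across miRNAs, which are not independent replicates. The median SD of an entry over the 12 arrays was 0.10 log2 units, and 12.7% of the tested values lay at the floor of 21.9 intensity units. Intensities of different miRNAs depend on their probes and are not set against each other. The number of arrays limits the precision of every value below.

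The first question was whether liver miRNAs follow a 24-h rhythm, as the purpose given for the series, the control of the circadian clock by miRNAs after transcription, implies. No entry passed the test for a 24-h rhythm, and the fitted rhythms of the liver's well-known miRNAs were small. miR-122, a hepatocyte miRNA with roles in lipid metabolism, had a mean intensity of 31540, with a fitted peak-to-trough fold of 1.03 and an upper 95% limit of 1.14. The fold was 1.02 (upper limit 1.11) for let-7a, a member of a family that restrains growth genes, and 1.04 (upper limit 1.13) for miR-22. It was 1.12 (upper limit 1.29) for miR-21, which is induced in injured and regenerating liver, and 1.06 (upper limit 1.30) for miR-378, which lies within a gene of a metabolic coactivator.

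The 10 entries with the smallest p-values did not pass either. miR-720, an entry that derives from a transfer RNA, had a peak-to-trough fold of 1.13 (upper limit 1.25) with its fitted maximum 3.91 h after lights on. miR-365 and miR-148a each had a fold of 1.08, with upper limits of 1.15 and 1.16. Among miRNAs of other cell types, miR-143 of smooth muscle and fibroblasts reached a fold of 1.34 (upper limit 1.75) and miR-199b* of mesenchymal cells 1.42 (upper limit 2.07). The epithelial miR-200a, with 3 arrays at the floor, was fitted at 1.56, and miR-338-3p at 1.19 (upper limit 1.40). For miR-20a and miR-92a of the miR-17~92 clusters the folds were 1.09 and 1.12, and for let-7e the fold was 1.21 (upper limit 1.5).

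With limma's moderated F test of a 24-h cosine and sine, 0 of 139 entries had an adjusted p under 0.05, the smallest being 0.908, and 5 had an unadjusted p under 0.05 against 6.95 expected by chance. A permutation test of the 12 time labels gave 6 entries at an unadjusted p under 0.05 and 0 after adjustment, the smallest adjusted p being 0.972. With the slide as a block the limma count was 0, with 5 at an unadjusted p under 0.05. It was 0 among the 8 arrays of slide 1, with 4; the 4 arrays of slide 2 are too few for this test. Limits can be given for the 109 entries that were never at the floor. Of these, 92 had an upper 95% limit of the peak-to-trough fold under 1.5 and 104 under 2, and the median upper limit was 1.25. Of the 63 entries with a mean intensity above 100, 58 had a limit under 1.5 and 61 under 2. Staying above the floor does not by itself show a specific signal. The herpesvirus entries mcmv-miR-M23-1-5p, mcmv-miR-m88-1 and mghv-miR-M1-2 did so at mean intensities of 150, 86.3 and 29.9, though uninfected liver has no template for them. The means of miR-143 (43.4), miR-199b* (29.7) and miR-338-3p (26.6) lay below that of mcmv-miR-m88-1. The folds and limits given for entries this dim need not reflect the named miRNA. All limits here and below hold for the scaling used and leave out the uncertainty of the scaling, which is described under light against dark. In simulated data with 20 of the 139 entries made rhythmic, this test recovered 33% of rhythms of 1.2-fold, 73.5% of 1.5-fold and 93.5% of 2-fold. The simulated entries here and below were independent of each other and had no floor, unlike the real ones.

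**Figure D1:**
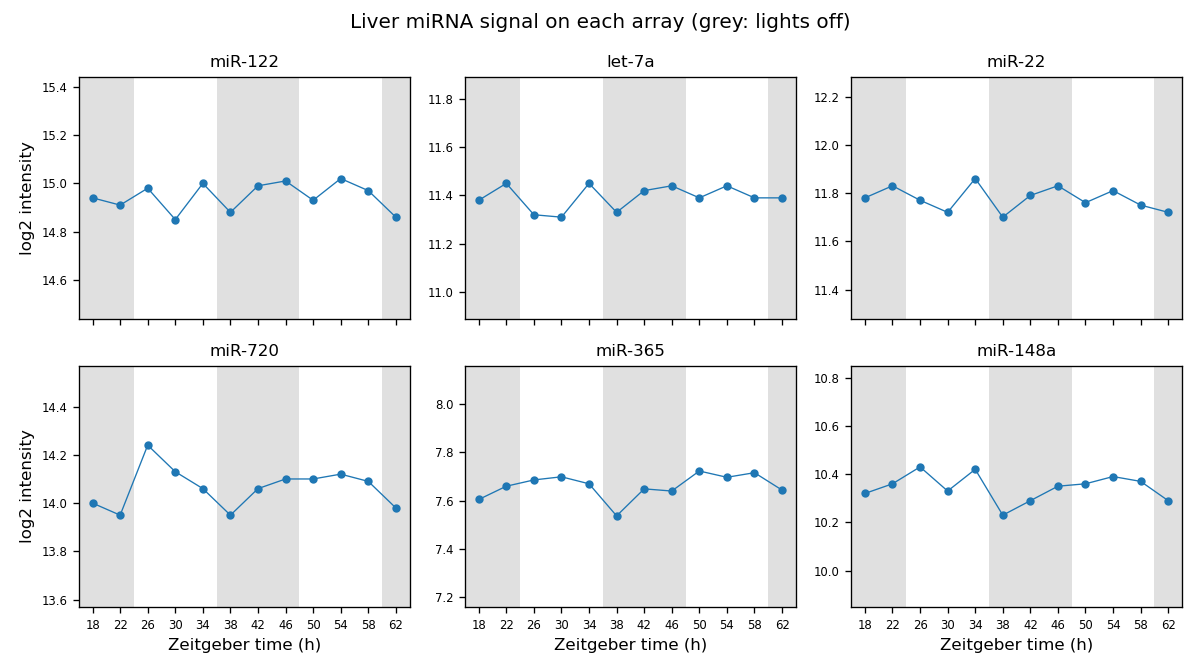
Log2 intensity (vertical axis, a span of about 1 unit in each panel) of 6 miRNAs on each of the 12 arrays against zeitgeber time in hours, 1 point per pool of 2 livers, with the dark hours in grey. miR-122, let-7a and miR-22 had fitted peak-to-trough folds of 1.03, 1.02 and 1.04; miR-720, miR-365 and miR-148a lay below their light mean on 6 of 6 dark arrays without passing the adjusted test.

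**Figure D2:**
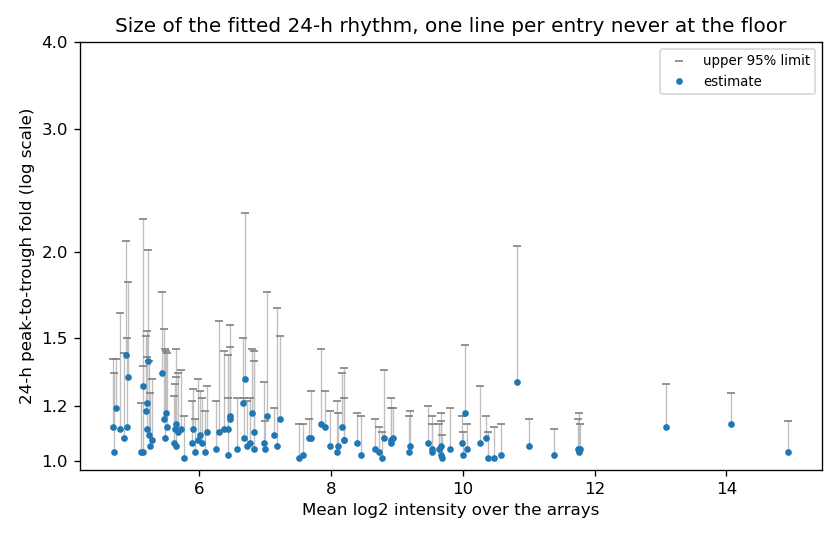
Fitted 24-h peak-to-trough fold (log-scaled vertical axis) against the mean log2 intensity for the 109 tested entries that were never at the floor, with points for the estimates and ticks for the upper 95% limits. The median estimate was 1.07 and the median upper limit 1.25.

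A list of 30 miRNAs that the literature ties to the clock, as rhythmic or as regulators of clock genes, was chosen before the data were examined, and 21 of its members could be tested. None passed: 0 had an adjusted p under 0.05 in limma over all 139 entries, 0 when adjusted over the list alone (smallest 0.830), and 0 had an unadjusted p under 0.05. miR-192 and miR-194, which are made from shared transcripts and have been reported to target Period genes, both had a peak-to-trough fold of 1.04, with upper limits of 1.15 and 1.13. For miR-27b and miR-142-3p, both reported to repress Bmal1, the folds were 1.07 (upper limit 1.23) and 1.12 (upper limit 1.34). The folds of miR-29a, miR-29b and miR-29c were 1.05, 1.06 and 1.04, those of miR-30a and miR-24 1.02 and 1.04, and those of miR-103, miR-16, miR-20a and miR-19b 1.01, 1.01, 1.09 and 1.08. miR-185 had a fold of 1.18 (upper limit 1.51), miR-34a 1.11 (upper limit 1.44), miR-494 1.13 (upper limit 1.45), miR-212 1.07 (upper limit 1.36) and miR-455 1.08 (upper limit 1.43). miR-122 is given above. Over the 19 members never at the floor, 18 had an upper limit under 1.5 and 19 under 2. miR-181d, at the floor on 2 arrays, had a fold of 1.62, and miR-219, a miRNA of the brain's clock, was at the floor on all 12 arrays; neither has a limit. Of the members not tested, miR-132, miR-191, miR-155, miR-182, miR-183, miR-141, miR-17 and miR-206 were detected on 0 arrays and miR-96 on 3.

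The second question was whether levels differed between light and dark, which for nocturnal mice also separates rest from activity and feeding. The smallest p-values belonged mostly to entries with slightly lower means in the dark, and none passed the adjusted test. miR-720 measured 14.12 ± 0.06 (SD, n = 6) in the light and 14.01 ± 0.06 (SD, n = 6) in the dark on the log2 scale, a dark over light fold of 0.922 (95% interval 0.873 to 0.973), lower on 6 of 6 dark arrays. Counts of dark arrays, here and below, set each against the light mean, so single arrays of both groups can overlap. For miR-720 the dark ZT46 array (14.1) stood above the light ZT34 array (14.06). miR-148a, a miRNA enriched in hepatocytes, measured 10.38 ± 0.04 against 10.31 ± 0.05 (SD, n = 6 each), a fold of 0.948, and miR-365 measured 7.70 ± 0.02 against 7.62 ± 0.05 (SD, n = 6 each), a fold of 0.949, each lower on 6 of 6 dark arrays. miR-1897-5p had a fold of 0.855, lower on 6 of 6 dark arrays, but lay at the floor on 6 of the 12 arrays. miR-338-3p, which lies within a neuronal kinase gene, had a fold of 1.12 (95% interval 1.03 to 1.23), higher on 5 of 6 dark arrays.

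miR-122 measured 14.96 ± 0.06 in the light and 14.93 ± 0.06 in the dark (SD, n = 6 each), a fold of 0.982 (95% interval 0.93 to 1.04). The folds of let-7a, miR-21, miR-22 and miR-378 were 1.01, 0.940, 0.998 and 0.940. Of the clock-related miRNAs, 18 had a lower and 2 a higher mean in the dark, with a median difference of -0.03 log2 units, and 0 passed when adjusted over the list alone. Relative to the median of all entries the mean of this list differed by -0.01 with the scaling used and by 0.20 with normexp. The list's own difference with normexp was -0.16, so the sign there came from the median. All of these values rest on the scaling between arrays. All-probe scaling took the 75th percentile over all probes, but only 16.5% to 19.6% of spots on an array lay well above background. That percentile thus fell among probes near background, so shifts with all-probe scaling need not reflect the signal of the miRNAs. The median of all tested entries moved by -0.02 log2 units between light and dark with the scaling used, by 0.38 when arrays were scaled on all probes and by -0.36 with another background correction (normexp). Relative to that median, miR-720, miR-365 and miR-148a were lower in the dark with the scaling used, with all-probe scaling, with quantile normalization and with no scaling, and higher with normexp (0.27, 0.12 and 0.36). Without taking off the median, they were lower in the dark with normexp (-0.095, -0.242 and -0.0036) and higher with all-probe scaling (0.312, 0.353 and 0.353). Their higher values relative to the median with normexp thus came from the median and do not show a rise in the dark. With normexp the dim miR-219 and miR-338-3p moved by -0.428 and -0.41, and the bright miR-122 and miR-192 by -0.00559 and 0.00727. Among these, the normexp median (-0.36) lay near the dim entries. Values relative to it, here and below, need not reflect the signal of bright miRNAs. miR-338-3p was higher relative to the median except with all-probe scaling (-0.05) and normexp (-0.05).

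In limma, 0 of 139 entries passed an adjusted p of 0.05 between light and dark. The smallest adjusted p was 0.437, shared by miR-720, miR-365, miR-148a, miR-338-3p and miR-1897-5p, whose folds and array counts are given above. At an unadjusted p under 0.05 there were 11 entries, 3 higher and 8 lower in the dark; without scaling the split was 5 higher and 1 lower, and with all-probe scaling 7 higher and 0 lower. With the slide as a block the count was 0, and it was 0 among the 8 arrays of slide 1, with 7 and 5 entries at an unadjusted p under 0.05; slide 2, with 1 dark array, holds too few for a comparison. Leaving out the ZT30 array gave 2 entries past the threshold, miR-101b and miR-1895. In simulated data the test recovered 60.8% of differences of 1.2-fold and 89.5% of 1.5-fold. The difference between dark and light did not differ detectably between cycles, with 0 entries past an adjusted p of 0.05 for the interaction in limma and 3 at an unadjusted p under 0.05.

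Differences between clock times of any shape were tested next. The entries with the smallest p-values were miR-338-3p, miR-143, miR-148a, miR-1897-5p and miR-689, and none passed. miR-338-3p measured 4.60 ± 0.01 log2 units (SD, n = 2) at 2 h after lights on and 4.92 ± 0.11 (SD, n = 2) at 22 h, and its clock-time means spanned 1.24-fold. The means of miR-143 spanned 1.46-fold, from 5.20 ± 0.04 (SD, n = 2) at 10 h to 5.75 ± 0.31 (SD, n = 2) at 22 h. miR-148a spanned 1.10-fold, miR-689 1.52-fold and miR-1897-5p 1.33-fold. In limma's F test over the 6 clock times 0 of 139 entries passed (smallest adjusted p 0.795), and 5 had an unadjusted p under 0.05.

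Single arrays could create calls in this test, because leaving one out leaves the other as the lone array of its clock time, assumed to vary like the rest. Without the ZT26 array 7 entries passed in limma, all of them highest on the ZT50 array: miR-715, miR-197, miR-296-5p, miR-878-3p, miR-487b, miR-30c-2* and mcmv-miR-m22-1. Of these, miR-296-5p was never at the floor, miR-197 lay at the floor on 10 arrays and the other 5 on 11, so that their spread was close to 0; miR-715, for example, measured 39.5 intensity units at ZT50 and the floor of 21.9 on every other array. Without ZT46 2 passed (miR-143 and miR-29b), without ZT54 1 (miR-362-3p), without ZT58 1 (miR-680), and on slide 1 alone 2 (miR-362-3p and miR-680, at the floor on 9 and 10 arrays of the 12). In simulated data the test recovered 52.5% of changes of 1.5-fold and 79.8% of 2-fold.

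If the livers kept a daily profile, arrays taken 24 h apart should resemble each other more than other pairs. They did not. The deviations of the 139 entries from their means correlated with a mean r of -0.131 over the 6 pairs of arrays 24 h apart and -0.0769 over the other 60 pairs, taken across miRNAs, which are not independent. An exact test over all 10395 ways of pairing the 12 arrays gave a one-sided p of 0.599. With each miRNA standardised first, the means were -0.14 and -0.0798, and the exact one-sided p was 0.809.

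Levels in the second cycle were then set against the first, within clock times. miR-126-3p, the miRNA of endothelial cells, measured 10.34 ± 0.04 log2 units in cycle 1 and 10.42 ± 0.03 in cycle 2 (SD, n = 6 each), a fold of 1.05, higher in 5 of 6 pairs. let-7e had a fold of 1.10, higher in 4 of 6 pairs, and miR-712 a fold of 1.19, higher in 5 of 6 pairs. The herpesvirus entry mcmv-miR-m88-1 had a fold of 1.11, higher in 5 of 6 pairs, and miR-188-5p, at the floor on 7 arrays, had a fold of 1.16, higher in 4 of 6 pairs. In limma 0 of 139 entries passed, the adjusted p of each of these being 0.865, and 5 had an unadjusted p under 0.05, all 5 higher in cycle 2. Slide 1 held 8 arrays, ZT18 to ZT46, and slide 2 held the 4 later ones, so slide and cycle overlapped in part. With the slide as a block the count was 0, with 5 at an unadjusted p under 0.05, and slide 1, with both cycles at 2 clock times only, holds too few arrays for this test. Scaling on all probes moved the median cycle difference to -0.50 and normexp moved it to 0.36, against 0.02 with the scaling used. The entries at an unadjusted p under 0.05 then turned to 0 higher and 48 lower in cycle 2 with all-probe scaling (smallest adjusted p 0.115 in limma) and to 0 higher and 10 lower with quantile normalization, and without scaling there were 0 higher and 1 lower. All-probe scaling rested on probes near background, as described under light against dark, so its count of 48 need not reflect the signal of the miRNAs. Relative to the median, the 5 entries named here stood higher in cycle 2 with the scaling used, with all-probe scaling, with quantile normalization, without scaling and with normexp, except miR-126-3p with normexp (-0.35). The own cycle difference of miR-126-3p with normexp was 0.0099 log2 units, so its negative value there came from the median. With normexp the cycle difference was 0.445 for the dim miR-219 and 0.023 for the bright miR-122. In simulated data the test recovered 54.5% of changes of 1.2-fold and 91.8% of 1.5-fold.

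A 12-h rhythm beside the 24-h one was the last test of single entries. The smallest p-values belonged to miR-23a, which shares a cluster with miR-27a and miR-24, to miR-107, to miR-338-3p, to miR-345-5p and to let-7d, entries picked out after their values were seen. Their fitted 12-h peak-to-trough folds were 1.10, 1.12, 1.15, 1.12 and 1.11. In limma 0 of 139 entries passed, the smallest adjusted p was 0.63, and 8 had an unadjusted p under 0.05. With normexp values miR-451 alone passed this test, the 24-h test and the time-of-day test. There limma's estimate of the prior degrees of freedom was infinite, so that the spread of miR-451 itself was set aside, and with its own variance its adjusted p was 0.589, 0.658 and 0.623. In simulated data the 12-h test recovered 71.5% of rhythms of 1.5-fold.

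Groups of miRNAs were followed through 22 lists chosen before the data were examined, of which 18 had at least 2 tested members. The miR-200 family of epithelial and bile duct cells, here miR-200a and miR-200b, averaged 4.58 ± 0.12 log2 units in the light and 4.91 ± 0.43 in the dark (SD, n = 6 each), higher on 4 of 6 dark arrays. Without the ZT22 array its dark minus light difference was 0.20 log2 units instead of 0.34, and miR-200a lay at the floor on 3 arrays and miR-200b on 2. The miR-15/16 family, which restrains cell division, averaged 7.61 ± 0.07 in the light and 7.67 ± 0.06 in the dark (SD, n = 6 each), higher on 5 of 6 dark arrays. Of its 6 members 4 had a higher mean in the dark, with miR-195 at 1.14-fold and miR-497 at 1.12-fold, while miR-16 stood at 0.993 and miR-15b at 0.966. A list of 10 entries that can follow RNA quality, miR-720 and miR-1897-5p among them, averaged 6.98 ± 0.14 in the light and 6.84 ± 0.12 in the dark (SD, n = 6 each), lower on 5 of 6 dark arrays.

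These 3 lists passed limma's camera test between light and dark at a preset correlation of 0.01, each with an adjusted p of 0.0329. None was past it with the correlation estimated from the data, each having an adjusted p = 0.777 with an estimated correlation. The estimated correlations of the miR-200, miR-15/16 and RNA quality lists were 0.939, 0.336 and 0.324, well above the preset. A preset below the correlation of the members makes the p-values of camera too small. The fry test gave adjusted p-values of 0.481, 0.560 and 0.481 for the miR-200, miR-15/16 and RNA quality lists. With the slide as a block 0 lists passed camera, each of the 3 having an adjusted p of 0.102, and within slide 1 the count was 0. On slide 1 the dark minus light differences of the miR-200, miR-15/16 and RNA quality lists were 0.39, 0.09 and -0.04 log2 units, and on slide 2, with 1 dark array and so no comparison of its own, they were -0.08, -0.06 and -0.30. Relative to the median of all entries, the miR-200 list stood 0.36 higher in the dark with the scaling used and 0.37 both with quantile normalization and without scaling, but 0.05 with all-probe scaling and 0.0044 with normexp. The miR-15/16 list stood between 0.08 and 0.19 higher under each of these scalings and corrections, quantile normalization and no scaling included, and the RNA quality list stood lower except with normexp (0.03). Without taking off the median, the normexp differences of the miR-200, miR-15/16 and RNA quality lists were -0.356, -0.167 and -0.334. With all-probe scaling 0 lists passed camera, and with quantile normalization the miR-200 list lost its call (adjusted p 0.0924) at a difference that was no smaller, while the miR-23/27/24 list passed (0.0329). Each list lost its call when certain single arrays were left out in turn. For the miR-200 list these were ZT38, ZT42, ZT50, ZT54 and ZT58, without which its dark minus light difference lay between 0.29 and 0.37 against 0.34 with all arrays, while without ZT22 it kept its call (adjusted p 0.0224). For the miR-15/16 list they were ZT18, ZT26, ZT30, ZT38, ZT42, ZT50 and ZT58, with differences between 0.05 and 0.06 against 0.06. For the RNA quality list they were ZT22, ZT38, ZT42, ZT50, ZT58 and ZT62, with differences between -0.15 and -0.11 against -0.14. Without ZT38 the miR-23/27/24 list alone passed (adjusted p 0.0365).

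No list showed a 24-h rhythm. By a permutation test of the 12 time labels, 0 of 18 lists passed (smallest adjusted p 0.754) and 0 had an unadjusted p under 0.05; in limma, 0 members of any list passed when adjusted over the list alone. The 10 hepatocyte miRNAs tested had a median peak-to-trough fold of 1.04, with miR-148a at 1.08, miR-802 at 1.5 and miR-101a at 1.05, and 9 of them had a lower mean in the dark, where the median of all entries was lower too. Relative to that median the mean dark minus light difference of the hepatocyte list was 0.0016 log2 units with the scaling used, -0.0088 with all-probe scaling, 0.02 with quantile normalization, 0.01 without scaling and 0.25 with normexp. The hepatocyte list's own difference with normexp was -0.107. The median fold was 1.06 over 14 miRNAs of lipid and glucose metabolism, with miR-26a at 1.06 and miR-143 at 1.34, 1.03 over the 9 of the let-7 family, 1.05 over the 5 of the miR-30 family, and 1.05 over miR-29a, miR-29b and miR-29c. It was 1.06 over 8 miRNAs of the miR-17~92 clusters, with miR-92a at 1.12, 1.07 over the 5 of the miR-23/27/24 clusters, with miR-23a at 1.07, and 1.04 over the miR-15/16 family.

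None of the markers of other cells in a whole liver passed either. The leukocyte list had a median peak-to-trough fold of 1.14 over 6 members, with miR-142-3p at 1.12 and miR-223, a miRNA of neutrophils and macrophages, at 1.04. The endothelial miR-126-3p and miR-126-5p stood at 1.01 and 1.02, and the mesenchymal list at a median of 1.06 over 7 members, with miR-199a-5p at 1.11. miR-451 and miR-144, which red blood cells carry in large amounts, had folds of 1.30 (upper limit 2.04) and 1.31 (upper limit 2.27). The median was 1.14 for miR-487b and miR-494 of the imprinted Dlk1-Dio3 region, where miR-487b lay at the floor on 11 arrays, 1.16 for the RNA quality list, and 1.12 for the 4 herpesvirus entries. Of the 2 neuronal miRNAs tested, miR-212 had a fold of 1.07 and miR-219 lay at the floor. The repeat-derived miRNAs of the Sfmbt2 cluster had 1 tested member, miR-467f, at the floor on all 12 arrays, and 34 of the 39 were detected on no array. The striated muscle list (7 entries), the pancreatic list (4 entries) and the miR-183 cluster (3 entries) had 0 tested members. In camera between light and dark the adjusted p was 0.451 for the clock-related, 0.457 for the hepatocyte, 0.962 for the leukocyte, 0.642 for the red cell, 0.658 for the endothelial, 0.133 for the mesenchymal and 0.0572 for the miR-23/27/24 list.

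**Figure D3:**
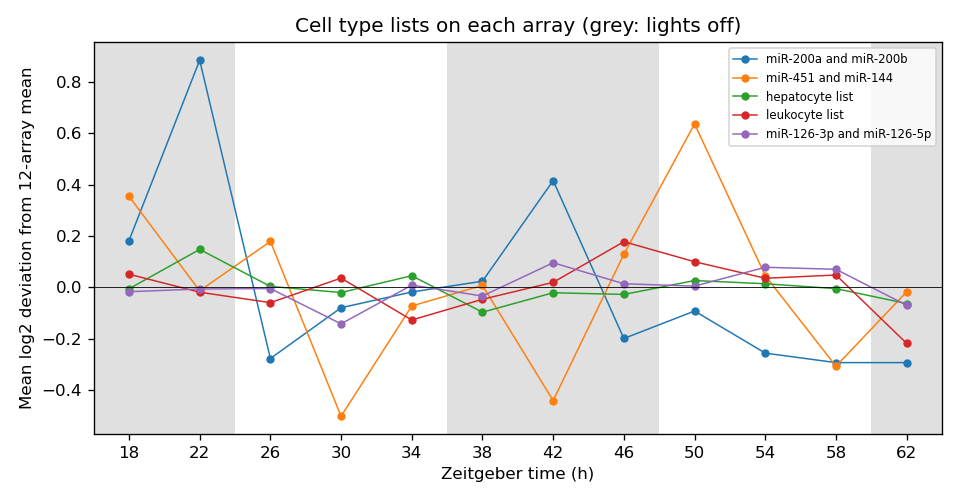
Mean deviation of 5 cell type lists from their 12-array mean (log2, vertical axis) on each array against zeitgeber time in hours, 1 point per pool of 2 livers, with the dark hours in grey. The miR-200 list stood at 0.89 on the ZT22 array, while the hepatocyte list stayed between -0.10 and 0.15.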

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

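The tests of single arrays, columns, scalings, cell types and separate orders for each entry below were chosen after the values had been seen, while the counts over other splits of the arrays were planned beforehand.

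Within the 6 light or the 6 dark arrays, a single array stood apart from the rest in 5 of 86 groups of values, where about 4.3 are expected by chance. On the ZT22 array the mean deviation of the hepatocyte list was 0.148 log2 units, with the next dark array at -0.01 and with miR-802 among its members, and that of the neuronal list was -0.179, with the next at -0.04. miR-712 measured 4.6 on the same array, with the next dark array at 5.1. The Dlk1-Dio3 list, miR-487b and miR-494, deviated by 0.323 on the ZT50 array, with the next light array at 0.03. On ZT50 miR-487b, at the floor on the 11 other arrays, deviated by 0.569 and miR-494 by 0.0761. The list thus stood apart mainly through 1 value of miR-487b above the floor. miR-1897-5p measured 4.53 on the ZT46 array and lay at the floor of 4.45 on the other dark arrays, so that any value above the floor would have stood apart; without this group the count was 4 of 85, with about 4.25 expected.

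The ZT22 array also carried a group of miRNAs at high levels: miR-802, a hepatocyte and pancreatic miRNA, the epithelial miR-200a and miR-200b, and the mesenchymal miR-199b* and miR-143 deviated by a mean of 0.931 log2 units there, against at most 0.166 on any other array. Time of day is argued against by the ZT46 array, taken 24 h later, where the same 5 miRNAs stood at -0.123. A lower share of hepatocytes would raise the miRNAs of every other cell type, yet the endothelial list stood at -0.00612 and the leukocyte list at -0.0188 beside 0.885 for the miR-200 list. Scaling is argued against as well by quantile normalization and no scaling, where the deviation was at least 0.938. It was at least that with all-probe scaling too, but a shift of the whole array was not taken off there. Normexp was not part of this test, so an effect of background correction stays open. On the same array the RNA quality list (-0.198) and the herpesvirus list (-0.214) stood at their lowest of the 12 arrays and the mesenchymal list, with miR-143 among its members, at its highest (0.189); a patch of bile duct or connective tissue in 1 of the 2 livers, the quality of the RNA or a fault of this array may lie behind the pattern, and none of these was tested.

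miR-181b, miR-181d, miR-99b*, miR-468, miR-718 and miR-705 were high together on the ZT26, ZT42, ZT46 and ZT58 arrays. ZT26, ZT42 and ZT58 are all the arrays of 1 column of the slides and had mean deviations of at least 0.243, so an effect of that column stays open for them, while for ZT46 (0.864) its own column is argued against, since the other arrays there reached at most -0.359. Time of day is not decided by the mean difference of 0.668 between arrays 24 h apart and 0.562 between other pairs (exact one-sided p of 0.681 for a smaller difference over all pairings). A second form of this test, on arrays picked by their own values, was dropped after it had been seen. ZT26, ZT42, ZT46 and ZT58 stood at 0.627, 0.243, 0.864 and 0.761. Their partners 24 h away, ZT50, ZT18, ZT22 and ZT34, stood at -0.293, -0.14, -0.121 and -0.601. The high levels of these 4 arrays thus did not recur at the same clock time. Since the arrays were picked by their own values, low partners can follow from the choice, and this does not decide on time of day. The 46 other dim entries had a median deviation of at most -0.00915 on the 4 arrays. Some of them lay at the floor on most arrays, such as miR-715 on 11 and miR-680 on 10. A small rise does not show there, so this test cannot decide on a shift of all dim entries. What these 4 arrays share stays open, and other features of their hybridisation could be a source as well.

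miR-451 and miR-144, made from a single transcript of red blood cells, varied together by up to 0.637 log2 units (ZT50) from their mean. Their mean difference was 0.367 between arrays 24 h apart and 0.369 between other pairs (exact one-sided p of 0.42), which does not decide whether time of day plays a part. Blood left in the liver is a candidate explanation that cannot be told apart from a change in the tissue, because miR-486, a red cell miRNA of another transcript, was detected on 4 arrays only.

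Other orders or splits of the same 12 arrays gave counts as large as the real ones, so chance cannot be excluded for any of the counts that follow. For the 24-h rhythm, 69 of 100 orders of the time labels gave at least the real 5 entries at an unadjusted p under 0.05 in limma, the highest other count being 20. Between light and dark, 16 of 100 splits gave at least the real 11, the highest other being 25. For the lists in camera, 12 of 100 splits gave at least the real 3 lists, the highest other being 6. Between cycles, 23 of 32 exchanges within clock times gave at least the real 5 entries, the highest other being 19. When each entry took an order of its own, which makes the entries independent, the highest counts were 17 for the 24-h rhythm, 13 between light and dark and 11 between cycles. The SDs of these counts were 2.7, 2.56 and 2.65, against 4.37, 5.44 and 4.58 when all entries shared an order. The counts thus spread more widely than those of independent entries, as where many miRNAs vary together over the arrays; the source of this was not tested.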

How the results depend on the processing

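Of 189 counts recomputed under alternatives, 170 stayed within 1.5 times the value reported; the runs without the ZT22 and ZT50 arrays, without entries always at the floor, with the slide column as a block, with unmoderated variances, and on single slides for the lists, the cycle, the 12-h rhythm and (slide 2) the 24-h rhythm were chosen after seeing the data. The runs on slide 2 alone, and that of the cycle on slide 1 alone, hold too few arrays to show stability. The value table holds the same intensities, so that alternative could not differ. Where the reported count was 0, staying within 1.5 times meant a count of 0 again. With normexp values the count was 1 for the 24-h rhythm, 1 for the time of day and 1 for the 12-h rhythm, miR-451 in each, because limma then set an infinite prior; with unmoderated variances each of these counts was 0. On slide 1 alone the time-of-day count was 2. The 3 lists past camera became 0 with an estimated correlation, which was 0.324 to 0.939 for these lists against the preset 0.01. They also became 0 with all-probe scaling, with the slide as a block, on slide 1 alone and without the ZT22 and ZT50 arrays. Apart from the smaller numbers of arrays, the cause of these other losses was not tested. With quantile normalization the count was 3, with the miR-23/27/24 list in place of the miR-200 list. Leaving out each array in turn gave 0 to 2 entries for light against dark, 0 to 7 for the time of day and 0 to 4 for the lists in camera (4 without ZT34 or ZT46, 1 without ZT38, 0 without ZT42, ZT50 or ZT58), and 0 for the 24-h rhythm, the cycle, the 12-h rhythm and the lists over 24 h. With the cycle as the replicate block the counts stayed at 0, and so did the cycle count with no replicate block. Among 2184 recomputed values of the clock-related miRNAs, of miR-122, let-7a, miR-21, miR-22 and miR-378, and of those with the smallest p-values, each in the comparisons it was named for (the 12-h rhythm left out), 1 passed a threshold, miR-143 for the time of day without ZT46 (adjusted p 0.0492 in limma, within a range of 0.0492 to 1 over the alternatives). Of 2046 with a direction, 167 turned, in 64 of 69 results, none of which had passed. The share of spots well above background, 16.5% to 19.6%, limits what can be said of dim miRNAs.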

Other observations

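The values in this part were picked out after they had been seen, except that the herpesvirus list and its test were fixed beforehand.

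Several further miRNAs differed between light and dark at an unadjusted p under 0.05 in limma without passing after adjustment (adjusted p between 0.496 and 0.581). miR-195, of the miR-15/16 family, had a dark over light fold of 1.14 and was higher on 6 of 6 dark arrays. miR-200a had a fold of 1.30 and was higher on 5 of 6, but its difference of 0.38 log2 units was 0.23 without the ZT22 array, and relative to the median of all entries it was 0.06 with all-probe scaling and 0.02 with normexp against 0.405 with the scaling used. miR-19b of the miR-17~92 clusters, miR-31 and miR-22*, the other arm of the precursor of miR-22, had folds of 0.95, 0.928 and 0.906, each lower on 6 of 6 dark arrays, though miR-19b stood higher relative to the median with normexp (0.26). The own normexp difference of miR-19b was -0.103 log2 units. miR-22 itself had a fold of 0.998.

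The herpesvirus entries, for which uninfected mouse liver has no template, lay on the same side as most of these. Their mean was 5.80 ± 0.12 log2 units in the light and 5.71 ± 0.09 in the dark (SD, n = 6 each), lower on 6 of 6 dark arrays, and the 3 tested entries never at the floor each had a lower mean in the dark, while mcmv-miR-m22-1 lay at the floor on 11 arrays. The list did not pass camera (adjusted p 0.428 at the preset correlation, 0.790 with an estimated correlation). Relative to the median of all entries its difference was -0.06 with the scaling used, and between -0.18 and -0.04 with all-probe scaling, quantile normalization, no scaling and normexp.

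Over the 139 entries the first principal component of the arrays held 35.6% of the variance, with ZT26, ZT46 and ZT58 at 1.77, 2.11 and 2.07 and ZT34 at -1.55. The column of an array on its slide gave 0 entries past an adjusted p of 0.05 in limma, the smallest being 0.177, and 12 at an unadjusted p under 0.05, while the slide gave 0 and 3.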
